A study of Mus musculus with 4 samples.

How the data were processed

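RNA was measured in 4 libraries of CD11b and CD200R1 positive myeloid cells, sorted by flow cytometry from cutaneous squamous cell carcinomas grown in their tissue of origin in FVB/N mice. Of these, 2 libraries came from wild-type tumours (WT), in which the tumour cells carry CD200. The other 2 came from EpiKO tumours, in which Cd200 was removed from the epidermis with K14Cre. Per the labels' protocols, mRNA was enriched by poly-A selection and libraries were made with an Illumina TruSeq RNA kit. Replicate numbers follow the order of the samples and pair nothing. The labels do not say whether the replicates came from separate mice or pools, so p-values of genes measure only the spread between these samples, which may be technical.

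Per the submitters' processing notes, the tools were bcl2fastq 2.17, STAR 2.5.2b, featureCounts 1.5.0-p3 and DESeq2, with build mm10. The gene annotation, the strand setting and the treatment of reads with several alignments are not given in the sources used here. The deposited values are a signal per gene: read counts that the authors divided by 1 size factor per library. This was read from the values, since all values of a library were whole multiples of the value of 1 read. Within a tolerance of 1e-06 reads, 100% of the values came out whole, which gave back the reads per gene and library. The table holds 23420 gene symbols, of which 7185 had no read in any library. All 4 columns of values were matched to a sample.

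The recovered reads assigned to genes numbered 15884132 and 21244158 in WT replicates 1 and 2, and 17398176 and 19318481 in EpiKO replicates 1 and 2. The value of 1 read was between 0.841 and 1.16, so a count of 3 reads stands for a value of 2.52 to 3.48. The 10 most abundant genes took between 6.79% and 9.44% of the reads of a library. Intervals for low counts are exact binomial 95% intervals. They cover counting error only, because reads were pooled over the 2 libraries of a group and the spread between libraries was left out. Reads without molecular identifiers are not independent molecules, so even the counting error may be understated.

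Because the deposited values are normalized, they were tested on the scale log2(value + 1). Genes with a value of at least 10 in at least 2 libraries were kept, which left 12463 genes. EpiKO was compared with WT by limma 3.58.1 in R 4.3.3 with a trend and robust empirical Bayes moderation, and p-values were adjusted by the Benjamini-Hochberg method over the tested genes. A gene was called at an adjusted p under 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. Standard errors are the moderated ones, and no covariate was used because the labels give no batch, litter or sex. All p-values are two-sided. An exact permutation test of 2 libraries against 2 cannot give a p below 0.333, so all p-values rest on the model's sharing of the spread across genes.

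For gene lists, 29 lists with 545 entries were fixed before the data were examined, as were the tests, the named genes and the alternatives. Of the entries, 15 were found under another symbol through RefSeq synonyms and 8 were not found. Lists were tested with camera in limma with a preset correlation of 0.01 between genes, two-sided and Benjamini-Hochberg adjusted over the 29 lists. This test compares the members of a list with the other genes, so its p-values rest on the spread between genes and on the preset correlation. The same test with a correlation estimated per list, fry, and camera on ranks were alternatives. A p-value adjusted over the list alone was also computed for each member.

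The genes named in the results follow a rule of 3 parts. The first part is Cd200, Cd200r1 and Ctsk. The second part takes, in each direction, the 12 largest fold changes among called genes with a mean value of at least 50 and no overlap between the groups. The third part takes up to 4 members of each list with the smallest p, or up to 3 with the highest mean for lists of other cell types and for sex-linked genes. Any gene named outside this rule was chosen after its values were seen. The values of 1 gene that the rule names are not reported here. Coordinates are from GENCODE M21 on mm10, where 122 of the 123 named genes were located. Of the 26 genes of the first and second parts, 8 share exon sequence with a gene on the other strand, and reads of such pairs cannot be told apart where the strand was not used in counting. These are Fam5c, Add2, Slco2a1, Wnt7b, Ptprn, Amigo2, Cyp2s1 and Uchl1.

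The alternatives were pseudocounts of 0.5 and 5, no filter, a filter at 50, equal library totals, quantile normalization, limma without trend, leaving out each library in turn, a threshold of 0.1, and a minimum log2 fold change of 1. On the recovered reads, edgeR 4.0.16 (quasi-likelihood test, TMM) and DESeq2 1.42.0 (Wald test) were run as alternatives. Where 1 library was left out, the lone library of its group was assumed to vary like the other group.

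The scripts were tested on simulated counts. Each gene was drawn independently of the others, so the rates do not carry over to lists of correlated genes. The spread of a gene followed the trend with abundance, without a spread of its own and without differences between libraries of a group. The rates may therefore not hold for single genes of these data either. In 5 simulations of EpiKO against WT with 200 changed genes, limma recovered 54.2% of genes changed by 1 and 96.6% of genes changed by 3 on the log2 scale, and 4.78% of its calls were false. A simulated list of 12 genes lowered by 1 on the log2 scale was called in 5 of 5 simulations with the preset correlation, in 2 with fry and in 0 with an estimated correlation. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.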

Results

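The data are RNA-seq profiles of tumour-infiltrating myeloid cells that carry CD11b, a myeloid integrin, and CD200R1, the receptor for the surface protein CD200. The cells were sorted from cutaneous squamous cell carcinomas of FVB/N mice, with 2 libraries from WT tumours and 2 from EpiKO tumours. EpiKO stands for removal of Cd200 from the epidermis by a Cre recombinase under the keratin 14 promoter. The single comparison of the design, EpiKO against WT, asks which genes of the CD200R1 positive cells depend on CD200 carried by the tumour, and the series names cathepsin K as the gene of interest. Depth ranged from 15884132 to 21244158 reads assigned to genes per library. Values are normalised read counts, given as mean ± SD with n = 2 per group, or per library.

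Ctsk, which encodes the collagen-degrading protease cathepsin K, was about 24.0 times lower in EpiKO. It stood at 8850 ± 2585 (SD, n = 2) in WT and 366 ± 95.6 (SD, n = 2) in EpiKO, and fell by 4.58 on the log2 scale (SE 0.275, adjusted p = 0.0329 by limma with Benjamini-Hochberg adjustment). Both EpiKO libraries, at 434 and 299, lay below both WT libraries, at 10677 and 7022. The gene lies on chromosome 3 of mm10 from 95499256 to 95509362, on the plus strand, and shares no exon sequence with another annotated gene. Leaving out any 1 library kept the log2 fold change between -4.89 and -4.28, while the adjusted p by limma was then between 0.0676 and 0.162.

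Cd200, the targeted gene, had values of 92.7 and 59.7 in the WT libraries and 17.2 and 15.1 in the EpiKO libraries. Its log2 fold change was -2.14 (SE 0.371) and missed the threshold at an adjusted p of 0.0794 (limma). The sorted cells are not the cells in which K14Cre acts, so these values do not check the labels. Cd200r1 was measured at 318 and 293 in WT and at 1101 and 612 in EpiKO, a log2 fold change of 1.43 (SE 0.293, adjusted p = 0.115 by limma). Dok2, an adaptor protein downstream of the receptor, had a log2 fold change of 1.31 (SE 0.351), and its relative Dok1 one of 0.15 (SE 0.181). Of the 6 tested members of the CD200 axis list none was called over all genes, whereas 2 were higher and 1 lower when adjusted over the list alone, and the list was not called as a set (adjusted p = 0.662 by camera). Cd200 is on chromosome 16 of mm10 from 45382135 to 45409053, and Cd200r1 on the same chromosome from 44765736 to 44794978.

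Across the transcriptome, 52 genes were higher and 66 lower in EpiKO among 12463 tested (limma, Benjamini-Hochberg adjusted p under 0.05). Of the tested genes, 1949 had an unadjusted p under 0.05 where 623 are expected by chance. The 118 called genes had a median absolute log2 fold change of 1.99, and in all 118 the 2 groups did not overlap. Non-overlap held for 47.1% of tested genes, against 33.3% by chance. On a principal component analysis the first component took 61.9% of the variance and separated the groups, and Pearson's r across genes was 0.979 within WT, 0.977 within EpiKO and 0.949 to 0.954 between the groups. The number of calls depended on the tool and on each library: DESeq2 on the recovered reads called 814 genes, which included all 118, and edgeR called 120, of which 110 were shared. Most calls were lost when any 1 library was left out. All 118 genes kept their direction in those fits, but the non-overlap of the groups fixed this in advance. Xist, from the inactive X chromosome, and the epithelial keratin gene Krt8 were at higher values in both EpiKO libraries than in both WT libraries.

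**Figure D1:**
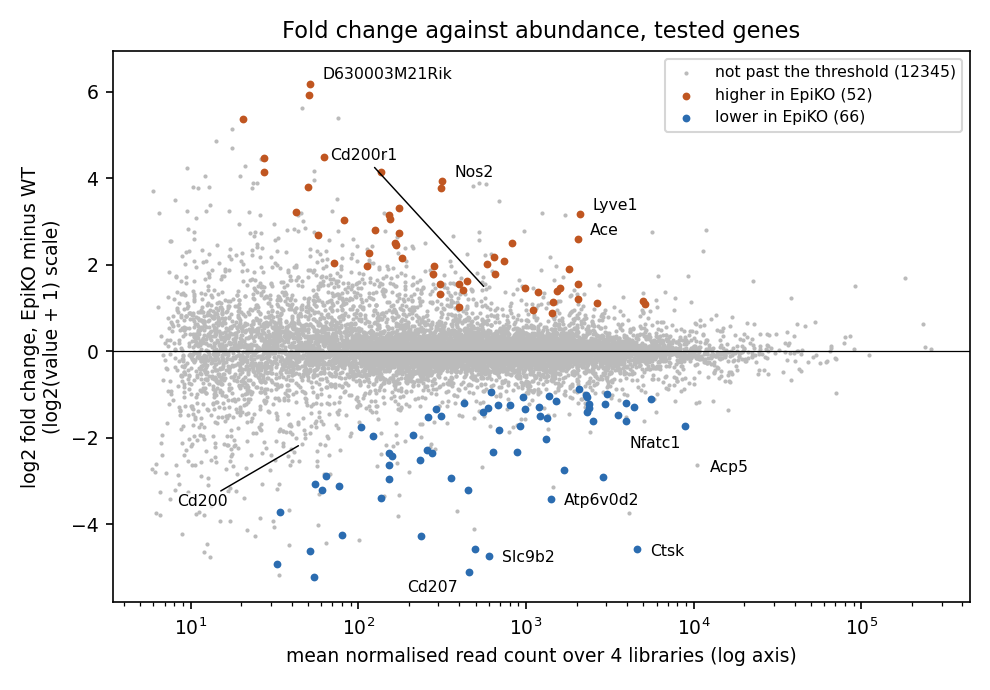
The horizontal axis shows the mean normalised read count over the 4 libraries on a log axis, and the vertical axis the log2 fold change of EpiKO minus WT for each tested gene. The 52 genes called higher and 66 called lower by limma are coloured, and Ctsk lies at -4.58.

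Genes of the osteoclast program, the set that bone-resorbing cells of the myeloid lineage use, moved down as a list in EpiKO (adjusted p = 5.53e-05 by camera). The call was lost with an estimated correlation, which was -0.028 between the members (adjusted p = 0.980 by camera). That setting also missed a simulated list of 12 uncorrelated lowered genes in 5 of 5 simulations. A call lost under it, here and below, therefore does not show that correlation between members undid it. Nfatc1, the master transcription factor of osteoclast formation, fell by 1.61 on the log2 scale (SE 0.136, adjusted p = 0.0334 by limma), from 5911 ± 631 to 1931 ± 179 (SD, n = 2). Atp6v0d2, a subunit of the proton pump, fell by 3.41 (SE 0.296, adjusted p = 0.0336 by limma), with WT libraries at 2694 and 2443 and EpiKO libraries at 324 and 178. Of 12 tested members these 2 were lower, 10 did not pass, and 7 were lower when adjusted over the list alone. Acp5, the tartrate-resistant acid phosphatase, stood at 21138 and 14871 in WT and at 2099 and 3864 in EpiKO (log2 fold change -2.64, adjusted p = 0.0540 by limma), and the fusion gene Ocstamp at 329 and 202 against 28.0 and 82.2. The fusion gene Dcstamp, outside the naming rule and chosen after its values were seen, showed no such gap, with a log2 fold change of -0.044 (SE 0.480). Clcn7, Ostm1 and Itgb3, chosen in the same way, were also nearly flat, at 0.14, -0.0043 and -0.16. In all, 11 members had a negative log2 fold change and 1 a positive one. Ctsk was not a member of this list. The 24 tested fibroblast markers had a median log2 fold change of 0.20.

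**Figure D2:**
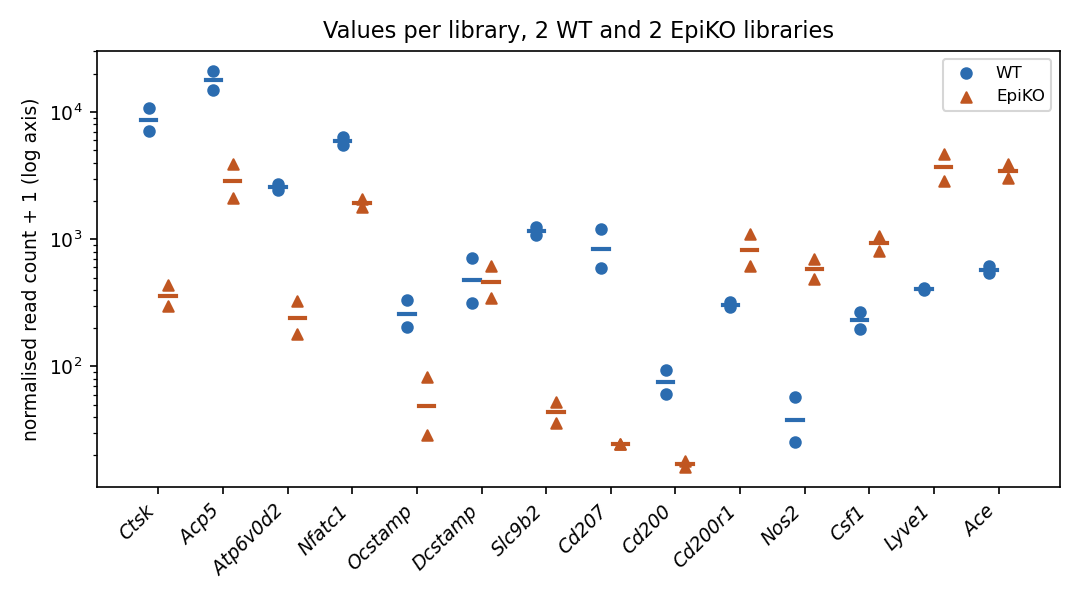
Points show normalised read counts + 1 on a log axis for each of the 2 WT libraries (circles) and 2 EpiKO libraries (triangles), and bars the geometric mean of each group. The 2 EpiKO values of Ctsk, 434 and 299, lie below the WT values of 10677 and 7022, whereas Dcstamp overlaps between the groups.

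Slc9b2, a sodium and proton exchanger, fell by 4.74 on the log2 scale (SE 0.236, adjusted p = 0.0329 by limma), from 1166 ± 129 to 43.3 ± 11.8 (SD, n = 2). Cd207, which encodes the C-type lectin langerin of Langerhans cells, fell by 5.10 (SE 0.368), from 1201 and 590 in WT to 23.7 and 23.6 in EpiKO. Also lower were Cyp2s1, a cytochrome P450, at a log2 fold change of -4.57, Itm2a at -4.27, Steap4, a metalloreductase, at -4.26, Bdh2 at -3.40, Fxyd2, a regulator of the sodium pump, at -3.22, and Uchl1, a deubiquitinase, at -3.20. Rufy4 and Fndc1 were near the floor in EpiKO, with 4 and 6 reads over both EpiKO libraries against 221 and 199 over both WT libraries. Their WT over EpiKO ratios were 53.5 (95% interval 20.6 to 198) and 32.1 (95% interval 14.5 to 88.6) from the reads, counting error only. The adjusted p of these genes lay between 0.0329 and 0.0396 (limma).

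Nos2, the inducible nitric oxide synthase, rose by 3.93 on the log2 scale (SE 0.448, adjusted p = 0.0471 by limma), from 56.8 and 24.4 in WT to 702 and 487 in EpiKO. Lyve1, a hyaluronan receptor of lymphatic endothelium and some tissue macrophages, rose by 3.18 (SE 0.244, adjusted p = 0.0334 by limma), from 405 ± 6.39 to 3780 ± 1278 (SD, n = 2). Slco2a1, a prostaglandin transporter, rose by 3.78, Wnt7b, a secreted Wnt ligand, by 3.32, and Add2, a cytoskeletal adducin, by 4.13. Itih5 rose by 4.48, Rundc3a by 3.80, Ptprn by 3.14, Scara3, a scavenger receptor, by 3.05 and Amigo2 by 3.03. The largest ratios belonged to genes almost without reads in WT. D630003M21Rik had 1 read over both WT libraries and 207 over both EpiKO libraries, a ratio of 214 (95% interval 37.9 to 8485, counting error only). Fam5c, now called Brinp3, had 2 and 197, a ratio of 102 (95% interval 27.8 to 846). The adjusted p of all these genes lay between 0.0329 and 0.0471 (limma).

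Inflammatory mediators moved up as a list in EpiKO (adjusted p = 0.00259 by camera), a call lost at an adjusted p = 0.980 with an estimated correlation. Of 17 tested members 2 rose, Nos2 and Csf1, the macrophage growth factor, and 15 did not pass. Csf1 rose by 2.00 on the log2 scale (SE 0.215, adjusted p = 0.0425 by limma), from 233 ± 51.1 to 933 ± 169 (SD, n = 2). When adjusted over the list alone 5 members were higher. The cytokine genes Il6 and Il1a had log2 fold changes of 2.57 (SE 0.454) and 2.19 (SE 0.432) with adjusted p of 0.0816 and 0.107 (limma).

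Genes of alternative macrophage activation moved up as a list (adjusted p = 0.00115 by camera), although none of its 20 tested members was called over all genes. The list call was lost with an estimated correlation, at an adjusted p of 0.980, and without WT replicate 2, at an adjusted p of 0.0854. When adjusted over the list alone, 4 members were higher and 1 lower. F13a1, a coagulation factor made by macrophages, stood at 25605 and 19996 in WT and at 51773 and 53702 in EpiKO (log2 fold change 1.22, adjusted p = 0.0551 by limma). The chemokine gene Ccl24 had a log2 fold change of 2.14 (SE 0.323), and the mannose receptor gene Mrc1 one of 0.67 (SE 0.162). Socs1, a brake on cytokine signalling, went the other way at -1.02 (SE 0.251).

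Chemokine genes were not called as a list (adjusted p = 0.238 by camera), and 1 of 22 tested members was called. Ccl7, a monocyte attractant, rose by 1.15 on the log2 scale (SE 0.141, adjusted p = 0.0471 by limma), from 3106 ± 337 to 6886 ± 724 (SD, n = 2). Adjusted over the list alone, 5 members were higher and 2 lower. Ccl6 was at 3412 and 2248 in WT and at 28464 and 13100 in EpiKO, and Ccl2 at 3831 and 3552 against 11988 and 7589. Cxcl13, a B cell attractant, was at 9932 and 5304 in WT and at 304 and 953 in EpiKO, a log2 fold change of -3.75 (SE 0.606, adjusted p = 0.0749 by limma).

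Glycolysis and hypoxia genes had the smallest list p, and moved up (adjusted p = 6.00e-09 by camera). The call was lost at an adjusted p = 0.980 with an estimated correlation, which was 0.457 between the members. Of 24 tested members 23 had a positive log2 fold change, with a median of 0.55. None was called over all genes, whereas 7 were higher when adjusted over the list alone. The oxidoreductase gene Ero1l stood at 1130 and 976 in WT and at 2968 and 2208 in EpiKO, and Adm, the gene of the vasodilator adrenomedullin, at 19.7 and 16.0 against 94.7 and 173. Egln3, an oxygen sensor, and Pfkl, a phosphofructokinase, had log2 fold changes of 2.24 (SE 0.341) and 0.75 (SE 0.129).

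Interferon-stimulated genes moved down as a list (adjusted p = 0.00149 by camera), with 26 of 32 tested members at a negative log2 fold change and a median of -0.40. The call was lost with an estimated correlation (adjusted p = 0.980 with an estimated correlation, which was 0.806 between the members), without EpiKO replicate 1 (adjusted p = 0.990) and without WT replicate 2 (adjusted p = 0.0996). None passed over all genes or when adjusted over the list alone. Ifit1 had values of 177 and 307 in WT and 78.6 and 127 in EpiKO, and the interferon regulator Irf7 had 1135 and 1490 against 504 and 899. The log2 fold changes of Isg15 and Ifit3 were -0.81 (SE 0.251) and -1.22 (SE 0.391).

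Cystatins and stefins, inhibitors of cysteine cathepsins, moved down as a list of 5 tested members (adjusted p = 0.00309 by camera). The call was lost at an adjusted p = 0.980 with an estimated correlation, and at 0.0732 without WT replicate 1. None was called over all genes, and 4 were lower when adjusted over the list alone. Cst3, cystatin C, stood at 30455 and 27011 in WT and at 18211 and 21549 in EpiKO (log2 fold change -0.53, SE 0.153). Cst7 had a log2 fold change of -1.40 (SE 0.358) and Cstb one of -0.47 (SE 0.167). Cst6, outside the naming rule and chosen after its values were seen, was at 350 in WT replicate 1 and 5.88 in WT replicate 2. In EpiKO it was at 15.1 and 24.6, so its lower mean rests on WT replicate 1, the library with high keratinocyte genes. The stefin BC100530 had 123 reads over both WT libraries, 98 in WT replicate 1 and 25 in WT replicate 2, and 1 over both EpiKO libraries. Its WT over EpiKO ratio was 119 (95% interval 20.98 to 4741, counting error only). BC100530 belongs to a cluster of near-identical genes, so its value is uncertain.

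Of 13 tested cathepsin genes only Ctsk was called, and 12 did not pass (adjusted p = 0.730 by camera). Adjusted over the list alone, 1 was higher and 1 lower. Ctsd, cathepsin D, had values of 36477 and 37340 in WT and 55413 and 54235 in EpiKO (log2 fold change 0.57, adjusted p = 0.135 by limma), Ctsl a log2 fold change of 0.34 (SE 0.174) and Ctsf one of -1.27 (SE 0.452). None of 26 matrix proteases and inhibitors was called, over all genes or when adjusted over the list alone (adjusted p = 0.337 by camera). Within it, Mmp9 had a log2 fold change of -1.24 (SE 0.280), Mmp8 one of 3.21 (SE 0.704) and Timp1 one of 0.73 (SE 0.190). The 26 lysosome and lipid genes were alike in having no call by either adjustment (adjusted p = 0.730 by camera). Among them, Lpl, lipoprotein lipase, was at 2660 and 2442 in WT and at 520 and 162 in EpiKO (adjusted p = 0.0854 by limma). Cd36 had a log2 fold change of -1.70 (SE 0.541) and varied within WT, at 672 and 2125 against 392 and 346 in EpiKO. Gpnmb and Gla had log2 fold changes of 1.60 (SE 0.394) and -0.51 (SE 0.167).

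Antigen presentation, complement, checkpoint and proliferation lists gave no call for any member, over all genes or when adjusted over the list alone. Adjusted p by camera was 0.917 for MHC class II, 0.858 for MHC class I, 0.730 for complement, 0.515 for checkpoint ligands and suppressive enzymes, and 0.238 for proliferation. For scale, H2-K1 had a log2 fold change of -0.49 (SE 0.118), H2-DMa one of 0.64 (SE 0.371), C2 one of 1.51 (SE 0.391) and Mcm6 one of -0.48 (SE 0.156). Cd274, the gene of PD-L1, was at 657 and 352 in WT and at 1701 and 1100 in EpiKO (adjusted p = 0.151 by limma), Havcr2 had a log2 fold change of -0.71 (SE 0.155), and Arg1 was at 10187 and 9175 against 54192 and 16393. Immediate early and heat shock genes were not called as a list either (adjusted p = 0.917 by camera), with 3 members higher when adjusted over the list alone. These were Egr2, Egr3 and Egr1, with log2 fold changes of 1.38 (SE 0.195), 1.57 (SE 0.238) and 0.79 (SE 0.160).

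Macrophage genes were abundant in all 4 libraries and were not called as a list (adjusted p = 0.210 by camera), with 1 of 20 tested members, Lyve1, called higher and 2 higher when adjusted over the list alone. Spp1, osteopontin, was at 47900 and 46436 in WT and at 158860 and 111359 in EpiKO (adjusted p = 0.0567 by limma). Of 13 monocyte genes 1 was called (adjusted p = 0.248 by camera). Ace, the angiotensin-converting enzyme, rose by 2.59 on the log2 scale (SE 0.160, adjusted p = 0.0329 by limma), from 576 ± 52.6 to 3487 ± 618 (SD, n = 2). Adjusted over the list alone, 2 monocyte genes were higher and 1 lower. F10 and Spn had log2 fold changes of 2.79 (SE 0.503) and -1.80 (SE 0.300). Of 15 dendritic cell genes Cd207 alone was called, by either adjustment (adjusted p = 0.730 by camera), and the abundant Naaa, Irf8 and Wdfy4 had log2 fold changes of -0.21, 0.21 and 0.32. The median, mean and test of a list differed in sign for 7 lists, none of them called: cathepsins, MHC class II, complement, immediate early and heat shock, dendritic cell, endothelial and sex-linked genes.

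**Figure D3:**
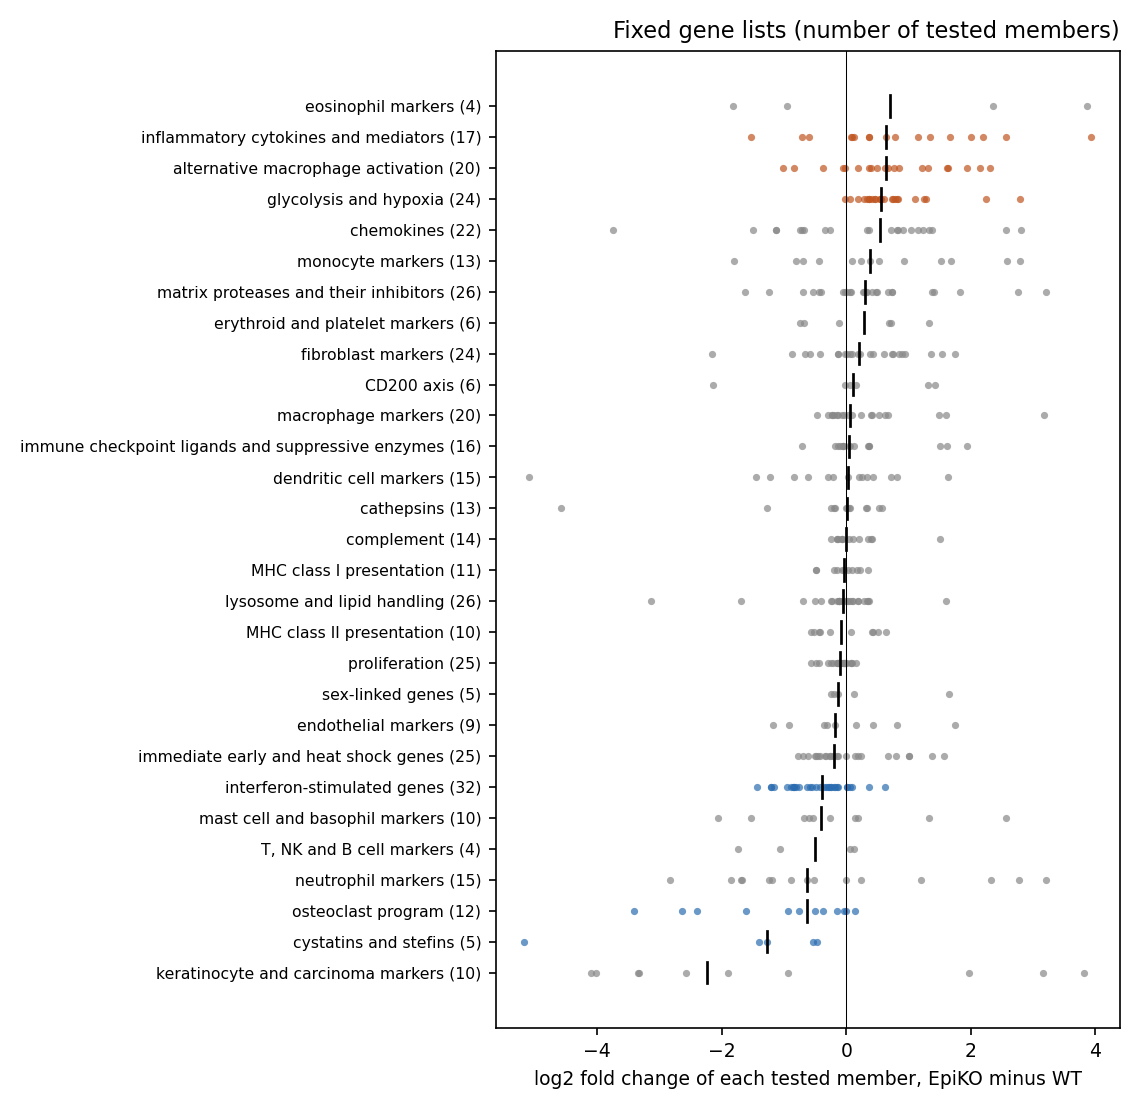
Each point is the log2 fold change, EpiKO minus WT, of 1 tested member of a fixed gene list, and the black bar is the list's median. Lists called up by camera with the preset correlation are orange, lists called down are blue and the 23 lists not called are grey.

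Transcripts of other cell types were present and differed between libraries. Keratinocyte genes were high in WT replicate 1 alone. Krt14 was at 1907 there against 28.6 in WT replicate 2 and 8.61 and 18.9 in the EpiKO libraries, and Krt5, chosen after its values were seen, was at 736 against 5.04, 7.54 and 7.56. Krt8, a keratin of simple epithelia, went the other way, at 446 and 234 in WT and 1999 and 4164 in EpiKO (log2 fold change 3.16, SE 0.459, adjusted p = 0.0616 by limma). Cdh1, E-cadherin, was at 547 and 361 against 4437 and 685. Of 10 tested keratinocyte and carcinoma genes none was called over all genes, and 2 were higher and 1 lower when adjusted over the list alone (adjusted p = 0.833 by camera). Of 24 tested fibroblast genes 2 were called higher, Col6a3 and Fbn1, and 4 when adjusted over the list alone (adjusted p = 0.0819 by camera). Both of these were named after their values were seen, with log2 fold changes of 1.54 (SE 0.153) and 1.36 (SE 0.154). Col3a1 was at 17999 and 11540 in WT and at 8619 and 10633 in EpiKO, Postn had a log2 fold change of -0.87 (SE 0.605), and Bgn one of 1.74 (SE 0.406).

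Markers of the remaining cell types gave no call over all genes. Adjusted p by camera was 0.660 for neutrophil, 0.660 for T, NK and B cell, 0.927 for mast cell and basophil, 0.983 for eosinophil, 0.917 for endothelial and 0.917 for erythroid and platelet markers. When adjusted over the list alone, 2 members were higher and 1 lower for mast cells and basophils, 1 higher and 1 lower for eosinophils, 1 lower for endothelium, and none for T, NK and B cells or erythroid cells and platelets. The neutrophil list had 2 members higher and 3 lower when adjusted over the list alone, with Csf3r at a log2 fold change of -0.52 (SE 0.446). Cd4 was at 1755 and 575 in WT and at 100 and 893 in EpiKO, and Cd79b, of B cells, was at or below 76.5 in each library. Only 4 of the 22 T, NK and B cell genes in the deposited values reached the filter. The T cell genes Cd3d, Cd3e and Cd3g, chosen after their values were seen, were at or below 2.32 in each library. Cd4 alone therefore does not show T cells. Tpsab1, of mast cells, varied within groups from 228 to 10.1 in WT and from 106 to 9.45 in EpiKO. Ear1, of a family with near-identical members and so uncertain, was at 2224 in EpiKO replicate 1 and at 39.7 in EpiKO replicate 2. Eng, a receptor of endothelium and macrophages, had a log2 fold change of -0.92 (SE 0.149, adjusted p = 0.0704 by limma). Xist, expressed from the inactive X chromosome, was at 522 and 361 in WT and at 1228 and 1510 in EpiKO (log2 fold change 1.65, SE 0.217, adjusted p = 0.0543 by limma). The Y-linked Ddx3y was at 2310 and 1938 in WT and at 1843 and 1742 in EpiKO, so that every library held reads of both Xist and a Y-linked gene. The sex-linked list had 1 member higher when adjusted over the list alone (adjusted p = 0.941 by camera).

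**Figure D4:**
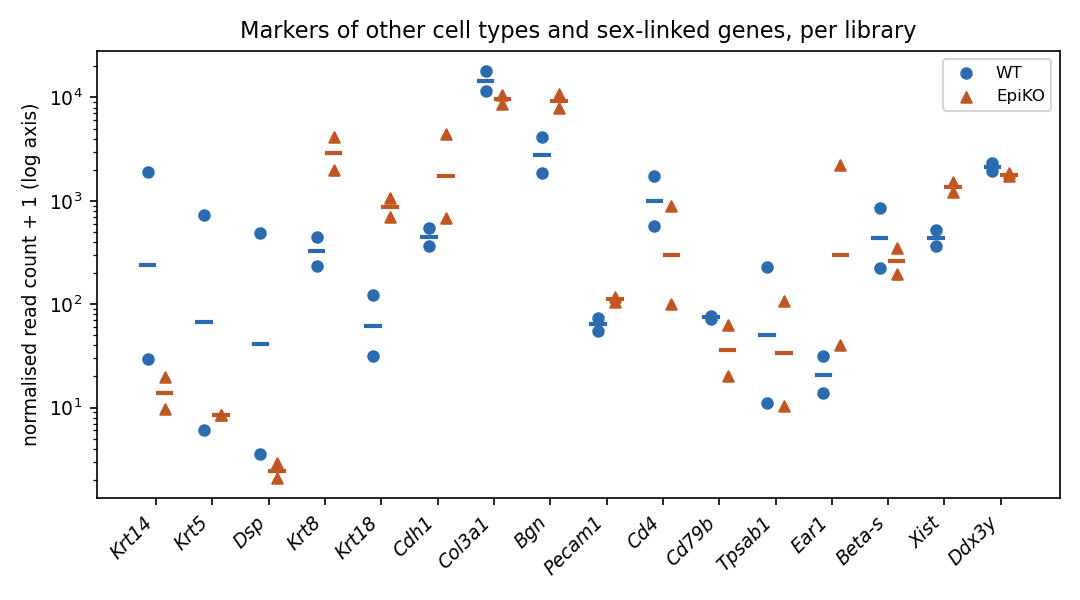
Points show normalised read counts + 1 on a log axis for marker genes of other cell types and sex-linked genes in the 2 WT libraries (circles) and 2 EpiKO libraries (triangles), with bars at the geometric mean of each group. Krt14 is at 1907 in 1 WT library and at 28.6 or less in the other 3, whereas Krt8 is higher in both EpiKO libraries.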

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

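Each of the 118 calls kept its direction under every scaling, pseudocount, filter and tool tried on all 4 libraries, as far as the gene was tested (115 of them with a filter at 50). Because the groups did not overlap for these genes, another pseudocount or filter, or leaving out 1 library, could not have reversed a direction. The counts of higher and lower genes moved by over 1.5 times under 3 settings and without 1 library. They were 14 and 24 with limma without trend (18 shared with the 118), 443 and 371 with DESeq2, which left 2767 adjusted p-values as NA, and 226 and 202 at an adjusted p under 0.1. Leaving out 1 library gave 0 to 2 higher and 0 to 4 lower genes, with 0 to 3 of the 118 called again. These fits have fewer samples and reuse libraries on which the 118 genes were selected, so they are no independent check of the calls. The counts with edgeR, other pseudocounts, filters and scalings, and a log2 fold change of at least 1 stayed within 1.5 times, and the share of calls that were higher went from 44.1% to 42.2% with equal library totals and 47.0% with quantile normalization. Except for fewer samples and the looser threshold, the cause was not tested.

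The 6 list calls became 0 with an estimated correlation and 0 with fry, and 5 to 12 without 1 library. All 6 stayed called with camera on ranks (adjusted p between 1.17e-07 and 0.0169), with a pseudocount of 5 and with quantile normalization. Each of these settings kept the preset correlation. With an estimated correlation each of the 6 had an adjusted p of 0.980. With fry the adjusted p was 0.370 for the osteoclast program, 0.456 for cystatins, 0.895 for interferon-stimulated genes, and 0.548 for alternative activation, inflammatory mediators and glycolysis. The estimated correlation was 0.806 for interferon-stimulated genes, 0.457 for glycolysis and 0.310 for inflammatory mediators, against the preset 0.01. It was 0.125 for alternative activation, 0.115 for cystatins and -0.028 for the osteoclast program. The osteoclast list had an unadjusted p of 3.81e-06 by camera with the preset correlation and of 0.0397 with its estimated one. Its estimated correlation was below the preset one, so correlation between its members does not account for its lost call. The simulated list of 12 shifted genes was also missed with an estimated correlation in 5 of 5 simulations, at an adjusted p of 0.263 to 0.301, below the 0.980 of the measured lists. The setting with an estimated correlation thus missed a shifted list even where genes were not correlated. A call lost under it does not show that correlation undid the call. The simulated genes were drawn without correlation, unlike several measured lists, so the simulations cannot tell which correlation setting is right for these data. Without 1 library the adjusted p ranged from 2.15e-04 to 0.0732 for cystatins, from 1.96e-05 to 0.0854 for alternative activation and from 2.24e-11 to 0.990 for interferon-stimulated genes. The osteoclast, inflammatory and glycolysis lists stayed called without any 1 library. A filter at 50 added the chemokine, fibroblast and keratinocyte lists. The last turned to up (adjusted p = 0.00290 by camera) on 3 tested members, against 10 in the main test. Krt14, high in WT replicate 1 alone, did not pass that filter, whereas Krt8 did. Lists not called with all 4 libraries were also called without WT replicate 1 (7 lists), without WT replicate 2 (keratinocyte), without EpiKO replicate 1 (proliferation, macrophage and fibroblast) and without EpiKO replicate 2 (monocyte). The direction of 4 to 6 lists turned without 1 library, none of them among the 6 called. MHC class II was up without WT replicate 1 (adjusted p = 0.00447 by camera) and down without WT replicate 2 (0.0564), and proliferation was down (6.91e-09) and up (0.0710).

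None of the genes whose sign reversed was called. Klrb1c, at a log2 fold change of 0.13, turned to -0.0018 with quantile normalization, -0.051 with edgeR and -0.056 with DESeq2. Without 1 library the log2 fold change ranged from -0.66 to 0.92 for Klrb1c, -0.082 to 0.39 for Dok1, -0.17 to 1.20 for H2-DMb2, -0.17 to 1.03 for H2-DMb1, -1.35 to 0.30 for H2-Eb1, -1.20 to 0.16 for Csf3r, -0.58 to 0.053 for Hgf, -2.78 to 1.59 for Tpsab1, -1.78 to 0.041 for Postn, -1.72 to 0.22 for Beta-s and -0.29 to 0.0065 for Eif2s3y. No paired analysis was possible because the replicate numbers only follow sample order. Depth limits genes near the value of 3 reads, such as Rufy4 and D630003M21Rik, whose intervals are wide.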

Other observations

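Except for the splits of the samples and the values without 1 library, the tests in this part were chosen only after the results were seen. Some called genes outside the naming rule, chosen after their values were seen, belong to signalling pathways. Notch1 rose by 1.21 on the log2 scale (SE 0.111), the Wnt ligand Wnt5a by 2.15 (SE 0.236), the Wnt receptor Fzd7 by 1.40 (SE 0.154) and Inhba, a subunit of activin, by 2.81 (SE 0.232). The integrin genes Itgal and Itga1 rose by 1.91 (SE 0.148) and 2.73 (SE 0.206), and the complement receptor gene Vsig4 rose from a mean of 236 to 1058. Dusp2, Dusp4 and Dusp8, phosphatases that switch off MAP kinases, had log2 fold changes of -1.30 (SE 0.162), -1.24 (SE 0.146) and -1.53 (SE 0.169). The adjusted p of these genes lay between 0.0329 and 0.0471 (limma).

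Traf1, Nfkbie and Birc3, which are NF-kB target genes, were called lower at log2 fold changes of -2.33 (SE 0.139), -1.22 (SE 0.136) and -1.05 (SE 0.117). Whether NF-kB targets were lower in general cannot be told apart from a change of some of them, because the lists that hold such targets went different ways. Of 20 other NF-kB target genes, none called over all genes, 17 had a negative log2 fold change, with a median of -0.55, and camera gave p = 2.93e-05 with the preset correlation and p = 0.110 with an estimated correlation. The inflammatory list, which holds further targets, had a median log2 fold change of 0.64, with 14 members positive and 3 negative, and its call up was lost at an adjusted p = 0.980 with an estimated correlation. Among targets outside the 20, chosen after their values were seen, Nos2 and Il6 had log2 fold changes of 3.93 and 2.57, and Tnf, Il12b, Cd40, Ccl5 and Cxcl10 had -0.60, -1.53, -0.72, -1.13 and -1.50. Of these 7 only Nos2 passed the test over all genes.

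The first pattern weighed is the lower Ctsk in EpiKO. Fewer carried-over fibroblasts would have lowered all fibroblast genes as far as Ctsk, but 9 core fibroblast genes had a median log2 fold change of -0.13, between -0.87 and 0.21. Keratinocytes in WT replicate 1 are argued against by a log2 fold change of Ctsk of -4.28 without that library, and a loss of male cells as large as that of Ctsk by a median of -0.17 over 4 Y-linked genes, although Xist, at a log2 fold change of 1.65 (SE 0.217, not past the threshold), leaves a smaller difference in the mix open. Whether fewer cells belonged to an osteoclast-like subset or each cell expressed less cannot be told apart, because bulk values hold no cells (the osteoclast list had a median log2 fold change of -0.64). Loss of tumour CD200, the difference the design names, stays open as a hypothesis.

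The second pattern is the keratinocyte RNA of WT replicate 1. The summed value of 12 squamous keratinocyte markers was 5173 there, against 61.4 in WT replicate 2 and 34.5 and 48.2 in the EpiKO libraries, although the sort for CD11b and CD200R1 would remove such cells. Krt14 and Krt5 were at 1907 and 736 in that library. All 12 of 12 markers were at least 10 times higher in WT replicate 1 than in each other library, as carried-over keratinocytes would give. The count restates the pattern in the same library with markers of the same kind, so it adds no independent support. Of the 66 lower genes, 3 were over 2 times higher in WT replicate 1 than in WT replicate 2. Among these were Cd207, at 1201 against 590, and Itm2a, at 626 against 278. In the EpiKO libraries both genes were at 23.7 or less, below WT replicate 2 as well. No biological explanation was tested.

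The third pattern is the higher Krt8 and Krt18 of EpiKO, at 1999 and 4164 for Krt8 and 698 and 1074 for Krt18, against 446 and 234, and 121 and 30.3, in WT. Carried-over squamous keratinocytes are argued against, since the summed squamous markers reached at most 0.0172 of the Krt8 value in an EpiKO library. In WT replicate 1, where squamous markers were high, their sum of 5173 exceeded the Krt8 value of 446. Carcinoma cells without squamous keratins, which the sort for CD11b and CD200R1 would remove, cannot be told apart from expression in the sorted cells, because the values go both ways: Cdh1 had a log2 fold change of 1.97 and did not pass the test. Cdh1 was at 4437 and 685 in the EpiKO libraries, highest where Krt8 was lower, and Epcam was at 6.46 and 7.56, against 156 and 7.57 in WT.

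The 2 EpiKO libraries differed from each other for several genes. EpiKO replicate 1 was 56.0 times higher than EpiKO replicate 2 for Ear1, and Chi3l3 was at 39879 against 1898. Cd200r4 was at 39.8 against 1.89, and Cd200r2 at 34.4 against 1.89, with both at or below 1.68 in the WT libraries. These genes belong to families of near-identical members, so their values are uncertain. Fn1 was at 388550 against 170027, and Mmp8 at 3757 against 847. With 2 libraries in each group the samples can be split in 3 ways, too few for a share under 0.05: the real split gave 118 genes and the highest of the others gave 0 (limma, 133 and 432 genes at an unadjusted p under 0.05). In the other splits each group held 1 library of each genotype. A difference between genotypes then adds to the spread and holds calls down, so these splits do not measure false calls.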
